A study of Arabidopsis thaliana with 12 samples.

How the data were processed

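Leaf RNA of 12-day-old Arabidopsis thaliana plants grown in soil was sequenced, per the labels, as paired 100 bp reads from 12 libraries. Each library is a pool and counts as a biological replicate, 3 in each of 4 groups; the extraction protocol and design text speak of seedlings and name the wild type and the lines but not limyb-32. Reads were checked with FastQC, trimmed with Trimmomatic and aligned to TAIR10 with Bowtie2, per the submitters' processing notes, which also name edgeR and DESeq2 and give no versions. The deposited values are raw counts per gene in a single table. Strand handling, the counting program and the treatment of reads with several matches are not recorded. Column names were matched to groups by their spelling, and none was left out.

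Gene identifiers follow the Arabidopsis genome numbering, and gene symbols in the text stand for them. Of 27416 identifiers, 26719 matched the TAIR10.1 annotation, 10376 of these with a symbol; the 88 plastid and 122 mitochondrial identifiers did not match and are given as they are. The libraries held 28.8 M to 75.8 M counts, and 2404 genes had none in any library. Normalised levels are CPM computed here from the deposited counts. A floor of 3 counts over the 3 libraries of a group is 0.0225 CPM in Col-0, 0.0115 in limyb-32, 0.0152 in L1 and 0.0131 in L3.

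Counts were filtered with filterByExpr by group, leaving 21272 genes, scaled with trimmed-mean (TMM) factors and tested in edgeR 4.0.16 (R 4.3.3) with quasi-likelihood F tests in a single model of all 12 libraries. There were 6 pairwise comparisons and a test for any difference among the groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, an approximation. Organelle shares were compared with exact permutation tests. Tested on simulated data for L1 against Col-0, 38% of 50 genes changed by 0.5 (log2), 92% at 1 and 100% at 2 and at 3 were recovered, and 9 unchanged genes were called.

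Before the data were examined, 28 gene lists were fixed from general knowledge. They cover the NIK1 module, cytosolic and plastid ribosomes, translation factors, ribosome biogenesis, light harvesting, photosystems and electron transport, both of these joined as nuclear photosynthesis, the Calvin cycle, and chlorophyll synthesis. They also cover salicylic acid defence, pattern-triggered immunity, jasmonate, abscisic acid with osmotic and cold responses, heat and unfolded protein, morning and evening clock, cell cycle, flavonoids, glucosinolates, and iron deficiency. The rest are root, seed, flower and stomatal markers, plastid- and mitochondrion-encoded genes, and the 10 genes on each side of LIMYB. The identifier first written for NIG belonged to another gene and was corrected after values had been seen. Lists were tested with camera in limma 3.58.1 on log CPM (prior count 2, inter-gene correlation 0.01), adjusted over the 27 measured lists of a comparison, and again with an estimated correlation and with fry. Camera's preset correlation ignores most of the correlation among genes of a list, and the estimated correlation rests on few libraries.

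The genes named in the text followed a rule fixed before the data were examined. LIMYB, NIK1, NIK2, NIK3, RPL10A, RPL10B, RPL10C and NIG were named in every comparison. Against Col-0 the 6 highest and 6 lowest, and elsewhere the 4 highest and 4 lowest, were named among genes past the threshold with a symbol, a mean of 5 CPM in a group and all 3 libraries of one group beyond all 3 of the other, which chance gives for 10% of genes. Up to 4 members past the threshold with the lowest adjusted p were eligible per list. RHD6, IRT1, IMA3 and AT5G05900 were added for their floors after their values were seen.

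Alternatives were RLE factors, total-count scaling, organellar genes left out, no filter, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, a 2-fold minimum, DESeq2 1.42.0, each library left out, and a block for replicate number. Nuclear totals were added after the data were seen. Replicate numbers did not pair the libraries (18 same-number correlations from -0.108 to 0.103, 1 over 0.1), so the block was used only as an alternative.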

Results

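Messenger RNA was sequenced from 12 pools of Arabidopsis thaliana plants, 3 biological replicates in each of 4 groups. Col-0 is the wild type. The libraries labelled limyb-32 are described in the labels as a knockout of LIMYB, a MYB-like transcription factor placed downstream of the receptor-like kinase NIK1 and the ribosomal protein RPL10. LIMYB_L1 and LIMYB_L3, shortened to L1 and L3, are lines in which a YFP-tagged LIMYB gene was put back into limyb-32 plants by floral dip. The labels give leaf tissue and an age of 12 days, while the design text speaks of seedlings and does not name limyb-32. By its title the study asks how the module of NIK1, RPL10 and LIMYB acts on photosynthesis and translation. Total counts lay between 65.1 M and 75.8 M per library, except for L1 replicate 2 with 28.8 M. Plastid transcripts took 66.4% ± 1.05 (SD, n = 3) of counts in Col-0, 48.8% ± 0.337 in limyb-32, 49.4% ± 3.52 in L1 and 55.2% ± 0.997 in L3. Mitochondrial transcripts took 0.404% ± 0.0243, 1.19% ± 0.203, 0.643% ± 0.0669 and 0.574% ± 0.0205 in the same order. Each share differed from Col-0 with p = 0.1 (two-sided exact permutation test), the smallest p for 3 against 3. Most of the plastid fall was in ATCG00020 (45.0, 26.3, 30.2 and 34.3% in the same order).

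LIMYB (AT5G05800; TAIR10.1, chromosome 5, 1742994 to 1745245, minus strand) was present in every library. Its level in Col-0 was 7.63, 8.20 and 7.85 normalised CPM in replicates 1, 2 and 3. The libraries labelled limyb-32 held 26.0, 16.9 and 8.98 CPM, none below Col-0. L1 held 110.1, 96.0 and 91.5 CPM and L3 held 113.1, 128.6 and 119.5 CPM. LIMYB was therefore higher than in Col-0 by 1.13 ± 0.26 on the log2 scale in the libraries labelled limyb-32 (adjusted p = 0.0021), by 3.65 ± 0.28 in L1 (adjusted p = 1.71e-07) and by 3.93 ± 0.28 in L3 (adjusted p = 9.79e-08). Gene-level counts cannot tell the resident gene from the construct, nor an intact transcript from a part of one. The LIMYB level thus cannot test the knockout label, and every direction drawn from these 3 libraries holds for libraries of that label only.

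**Figure D1:**
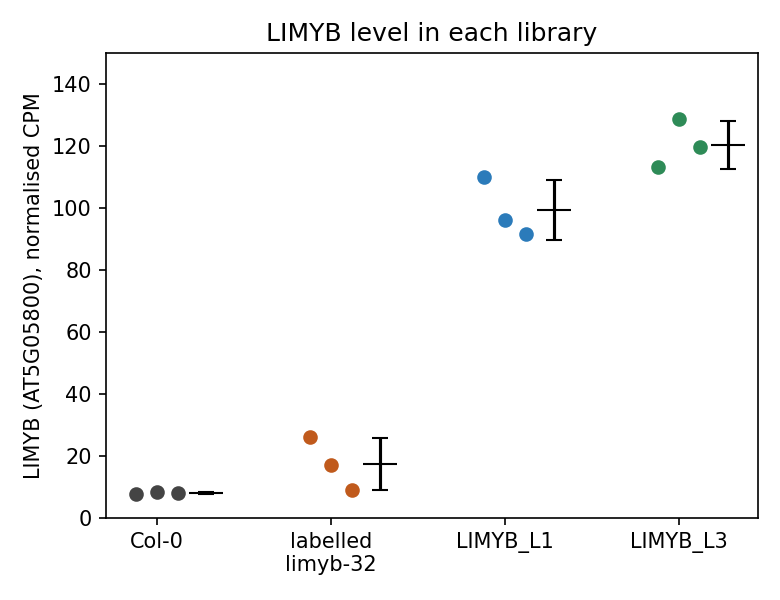
LIMYB level (normalised CPM, linear axis from 0) in each of the 12 libraries, as points, with the mean and SD of the 3 libraries of each group as a bar beside them. The libraries labelled limyb-32 lie between 8.98 and 26.0 CPM, above the 7.63 to 8.20 CPM of Col-0, and the L1 and L3 libraries lie between 91.5 and 128.6 CPM.

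Col-0, the libraries labelled limyb-32 and the lines separated on the first 2 principal components, while L1 and L3 lay close together. L1 replicate 1 correlated best with L3 replicate 2 (r = 0.984), and 11 of 12 libraries best with a library of their own group. The first component of the log CPM held 46.8% of the variance and the next 32.3%. The typical biological coefficient of variation was 0.125. Of 21272 tested genes, 16733 differed among the 4 groups (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, as for all gene calls). Values given for genes are log2 fold changes ± standard error with 3 libraries in each group. Values given for gene lists are medians of these over the measured members, with the adjusted p of limma's camera test, and no list fixed beforehand passed that test with an estimated correlation in any comparison. Where leaving out any single library moved a number of list members called by over 1.5 times and by at least 3, the range over the 12 libraries left out follows the number or its list. The changes are relative to the trimmed-mean scaling, since plastid transcripts took different shares of the groups. With scaling to the total count alone, the median of all genes moved by 0.92, 0.89 and 0.74 against Col-0 in the libraries labelled limyb-32, L1 and L3, by -0.18 in L3 against limyb-32 and by -0.14 in L3 against L1. Scaling to the total of nuclear genes moved the 3 medians against Col-0 by 0.33, 0.30 and 0.34. The share of called genes that were higher than in Col-0 went from 51.9, 50.7 and 50.2% to 94.6, 93.0 and 91.2% with total-count scaling and to 77.3, 72.3 and 75.2% with nuclear totals. In L3 it went with total-count scaling from 48.3 to 27.6% against limyb-32 and from 29.8 to 10.5% against L1. Relative to the median of all genes, which a scaling moves alike, the medians of the ribosomal list (-0.46, -1.02 and -1.19 against Col-0) and of the photosynthesis list (-1.01, -1.13 and -0.94) hardly depend on these scalings.

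**Figure D2:**
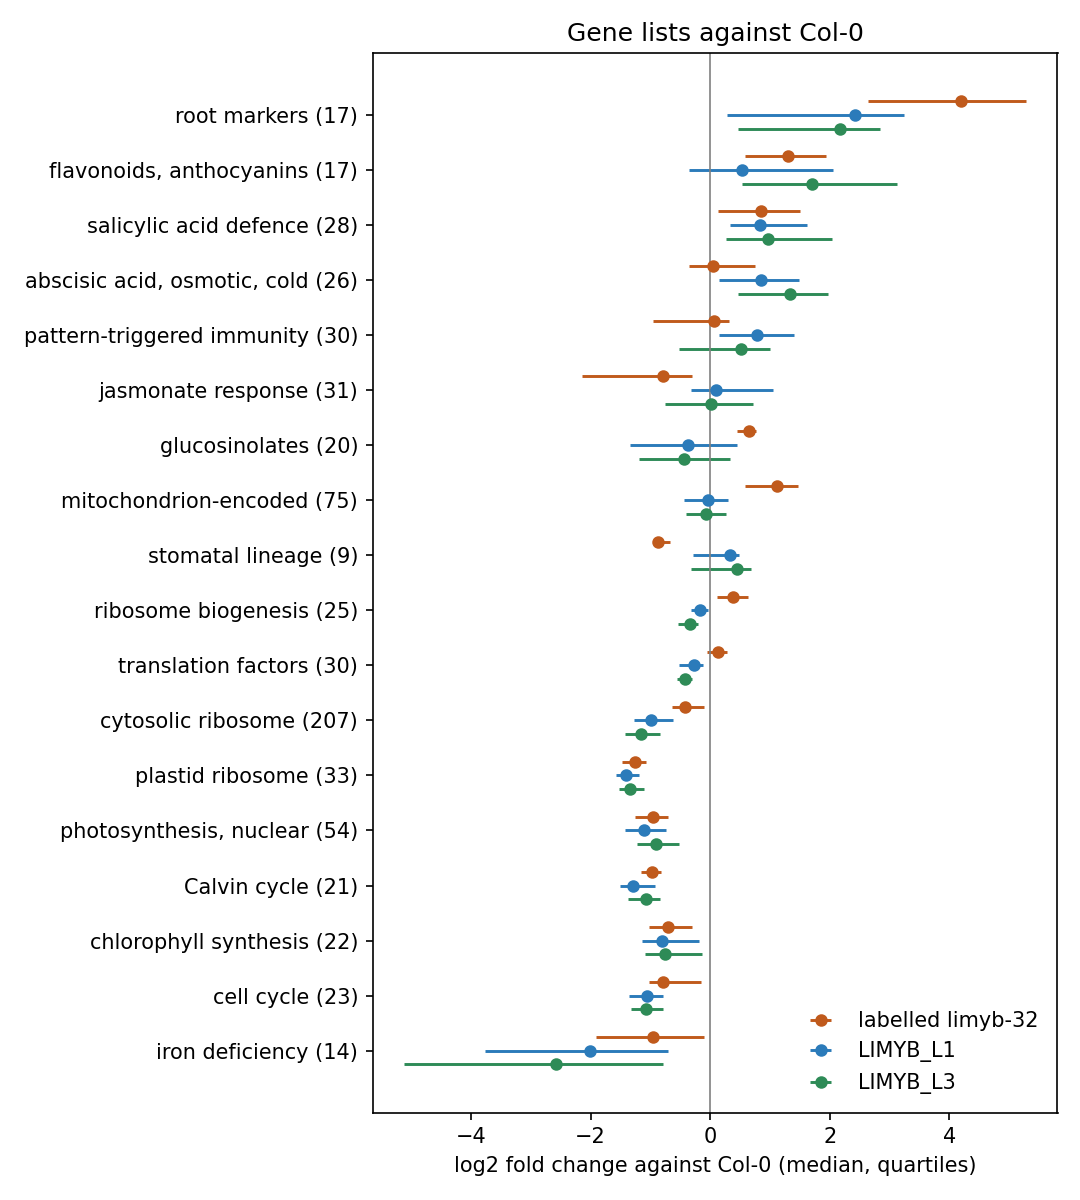
Median log2 fold change against Col-0 (x axis, points) with the lower and upper quartile of the members (lines) for 18 gene lists, number of measured members in brackets, in the libraries labelled limyb-32, L1 and L3. Lists for the cytosolic and plastid ribosome, photosynthesis, chlorophyll, the cell cycle and iron lie left of 0 in all 3 groups, and root markers lie right of 0. With total-count scaling the medians of the cytosolic ribosome, chlorophyll, jasmonate, cell cycle and stomatal lists turn positive in the libraries labelled limyb-32, as do those of the translation factor, ribosome biogenesis, glucosinolate and mitochondrion-encoded lists in L1 and L3 and that of the chlorophyll list in L1. Nuclear totals turn only the translation factor and ribosome biogenesis medians of L1 among the plotted lists of nuclear genes.

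The comparison of the libraries labelled limyb-32 with Col-0 asks what a change of LIMYB does. LIMYB was not lower there, and root RNA may be part of the change. PAP14 (AT2G46880), a purple acid phosphatase, rose by 8.38 and IPS1 (AT3G09922), an RNA of phosphate starvation, by 7.78. They had 4 and 6 counts in Col-0, too few for a standard error. The extensins EXT10 (AT5G06640) and EXT6 (AT2G24980) were higher by 6.41 ± 0.41 and 6.12 ± 0.36, the hydroxyproline-rich glycoprotein HRGP1 (AT3G54590) by 6.38 ± 0.36 and the arabinogalactan protein AGP3 (AT4G40090) by 6.21 ± 0.48. ASN1 (AT3G47340), an asparagine synthetase induced in darkness, fell by 5.68 ± 0.33, from 315.0 to 6.14 CPM. The defensins PDF1.3 (AT2G26010; -5.64 ± 0.75), PDF1.2c (AT5G44430; -4.66 ± 0.86) and PDF1.2A (AT5G44420; -4.56 ± 0.74), which respond to jasmonate and ethylene, fell as well. They are close copies, and gene-level counts do not show how reads were shared among them. OXS3 (AT5G56550), a stress tolerance gene, fell by 4.79 ± 0.13 and THA1 (AT1G08630), a threonine aldolase, by 4.78 ± 0.22.

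Within the NIK1 module, 2 of 8 genes were higher and 3 lower in the libraries labelled limyb-32. LIMYB (1.13 ± 0.26) and the receptor kinase NIK2 (AT3G25560; 0.27 ± 0.08) rose. NIK3 (AT1G60800) fell by 0.59 ± 0.10, and the ribosomal genes RPL10A (AT1G14320) and RPL10C (AT1G66580) fell by 0.31 ± 0.08 and 0.78 ± 0.10, but with total-count scaling these 3 values were 0.33, 0.61 and 0.15, and RPL10A was 0.02 with nuclear totals. NIK1 (AT5G16000) was at -0.22 ± 0.10 (adjusted p = 0.0873), RPL10B (AT1G26910) at -0.23 ± 0.11 (adjusted p = 0.0824) and the NIK-linked GTPase NIG (AT4G13350) at -0.18 ± 0.08 (adjusted p = 0.0615), none past the threshold. The list as a whole had a median of -0.22 (camera adjusted p = 0.208), or 0.70 with total-count scaling and 0.11 with nuclear totals.

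Ribosomal protein genes were mostly lower, while genes that build ribosomes were mostly higher. Of 207 genes for the cytosolic ribosome, 134 fell and 14 (range 8 to 14) rose in the libraries labelled limyb-32, with a median of -0.42 (adjusted p = 1.22e-11, adjusted p = 0.347 with an estimated correlation) that turned to 0.51 with total-count scaling. RPL23C fell by 1.11 ± 0.08 and RPS21C by 1.17 ± 0.09. All 33 genes for the plastid ribosome fell, with a median of -1.26 (adjusted p = 2.67e-14, adjusted p = 0.347 with an estimated correlation), among them PRPS13 at -1.82 ± 0.14. Among 25 ribosome biogenesis genes, 17 rose and 2 fell (median 0.38, adjusted p = 0.000962, adjusted p = 0.347 with an estimated correlation). TOZ and BOP1, nucleolar factors for pre-ribosomal RNA, rose by 0.84 ± 0.07 and 0.82 ± 0.07. Of 30 translation factors 9 rose and 4 fell (median 0.13, adjusted p = 0.356), with TIF3E1, an initiation factor subunit, at 0.32 ± 0.07 and the elongation factor subunit EF1BA2 at -0.60 ± 0.09.

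Photosynthesis genes encoded in the nucleus fell in the libraries labelled limyb-32. Of 54 genes 50 fell and none rose (median -0.96, adjusted p = 1.23e-14, adjusted p = 0.347 with an estimated correlation), but the median was -0.04 with total-count scaling. The photosystem subunits PSAN and PSBR fell by 2.04 ± 0.14 and 1.82 ± 0.14. Within this list, 31 of 33 genes for photosystems and electron transport fell (median -1.05, adjusted p = 7.93e-12, adjusted p = 0.347 with an estimated correlation). The other part, light-harvesting proteins, had 19 of 21 genes lower (median -0.81, adjusted p = 3.17e-07, adjusted p = 0.347 with an estimated correlation), which became 0.11 with total-count scaling; LHCB1.1 fell by 1.27 ± 0.11. In the Calvin cycle 19 of 21 genes fell (median -0.98, adjusted p = 1.88e-07, adjusted p = 0.347 with an estimated correlation), or -0.06 with total-count scaling. RBCS2B, a small subunit of Rubisco, was at -2.26 ± 0.19. In chlorophyll synthesis 18 of 22 genes fell (median -0.70, adjusted p = 4.48e-06, adjusted p = 0.347 with an estimated correlation), or 0.22 with total-count scaling. Root markers moved with these groups: all 17 rose (median 4.2, adjusted p = 7.36e-08, adjusted p = 0.347 with an estimated correlation), among them the root hair genes PRP3 at 5.29 ± 0.38 and COBL9 at 5.13 ± 0.41 and the phosphate transporter PHT1;1 at 3.19 ± 0.21. RHD6, a root hair regulator with 1 count over the Col-0 group, had a ratio of 135.4 with a 95% counting interval of 24.1 to 5368; intervals and floors cover counting error only.

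Defence pathways moved in different directions. Of 28 salicylic acid genes 15 rose and 1 fell in the libraries labelled limyb-32 (median 0.85, or 0.74 with GRX480 at its bound; adjusted p = 0.0121, adjusted p = 0.53 with an estimated correlation). The antimicrobial marker PR1 rose by 2.94 ± 0.54 and the immune regulator SAG101 by 1.12 ± 0.12. Of 31 jasmonate genes 18 fell and none rose (median -0.79, adjusted p = 0.00109, adjusted p = 0.53 with an estimated correlation), although the median was 0.13 with total-count scaling. JAZ9, a repressor of jasmonate signalling, fell by 2.51 ± 0.28 and the vegetative storage protein VSP1 by 4.06 ± 0.50. In pattern-triggered immunity 4 of 30 genes (range 1 to 5) rose and 11 fell, and the median (0.06) differed in sign from the mean (-0.32) and the camera direction (adjusted p = 0.241). ERF104 and WRKY40, transcription factors of the early response, fell by 2.2 ± 0.14 and 2.81 ± 0.29. Glucosinolate genes rose in 15 of 20 cases (median 0.66, adjusted p = 0.000962, adjusted p = 0.347 with an estimated correlation). MAM3, an enzyme of chain elongation, was at 1.86 ± 0.15. Flavonoid genes rose in 11 of 17 cases and fell in 1 (median 1.3, adjusted p = 0.0078, adjusted p = 0.385 with an estimated correlation). Chalcone synthase CHS was at 2.75 ± 0.24.

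Among 26 measured genes of abscisic acid, osmotic and cold responses, 9 rose and 6 fell (median 0.05, adjusted p = 0.739). RD29A was at 1.58 ± 0.11, ABF3 at 1.27 ± 0.12 and RD26 at -1.90 ± 0.19. Of 14 iron deficiency genes 8 fell and 2 rose (median -0.95, adjusted p = 0.0447, adjusted p = 0.476 with an estimated correlation, and 0.053 with a replicate block). The regulator BHLH101 was at -4.17 ± 0.43. Cell cycle genes fell in 17 of 23 cases and rose in 1 (median -0.80, adjusted p = 4.76e-05, adjusted p = 0.347 with an estimated correlation), or 0.12 with total-count scaling; the mitotic kinase AUR2 fell by 1.87 ± 0.15. Of 9 genes of the stomatal lineage 7 fell (median -0.87, adjusted p = 0.000653, adjusted p = 0.347 with an estimated correlation), or 0.05 with total-count scaling. Of 4 measured flower genes 3 fell (median -1.72, adjusted p = 0.0313, adjusted p = 0.347 with an estimated correlation), with SEP3 at -1.40 ± 0.11. Heat and unfolded protein genes (2 of 16 higher, 4 lower; median -0.21, or 0.71 with total-count scaling and 0.12 with nuclear totals), morning clock genes (4 of 12 lower; median -0.18, or 0.74 and 0.15) and evening clock genes (4 of 9 lower; median -0.55, or 0.38 with total-count scaling) did not pass as lists (adjusted p = 0.435, 0.0898 and 0.0605). Examples are HSP17.8 at -1.94 ± 0.45, the chaperone BIP1 at 0.49 ± 0.12 and RVE1 at -2.29 ± 0.19. None of the 10 seed markers was measured above the count filter in any group.

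Mitochondrion-encoded transcripts rose in 62 of 75 cases and fell in 1 (median 1.12, adjusted p = 2.45e-13, adjusted p = 0.347 with an estimated correlation), with ATMG01350 at 1.94 ± 0.10. Plastid-encoded transcripts fell in 39 of 74 cases and rose in 18 (median -0.42, adjusted p = 0.00306, adjusted p = 0.635 with an estimated correlation), or 0.50 with total-count scaling. ATCG00300 was at -2.63 ± 0.13. Of 18 measured genes beside LIMYB on chromosome 5, 5 rose and 5 fell (median 0.06, adjusted p = 0.944). AT5G05900 was at least 14.4-fold higher, with 84 counts against 0 over the groups, and the plastid protease EGY2 fell by 0.67 ± 0.11. In all, 12408 genes differed between the libraries labelled limyb-32 and Col-0, 6438 higher and 5970 lower. Of the 27 lists, 19 passed camera and 0 passed it with an estimated correlation. Adjusted over the list alone, the numbers of members called were equal in 15 lists and within 1 in 24, with the largest change, 3, in the mitochondrion-encoded list.

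The comparison of L1 with Col-0 asks what follows from adding back LIMYB, which stood 3.65 ± 0.28 above Col-0 there. PGAZAT (AT2G41850), a polygalacturonase, was at least 911-fold higher, with 4048 counts against 0 over the groups. CYP82C2 (AT4G31970), a cytochrome P450 of indolic defence compounds, rose by 9.98 ± 1.70 and PXMT1 (AT1G66700), a methyltransferase, by 9.68 ± 0.70. PAP14 rose by 8.90, IPS1 by 8.69 and PS2 (AT1G73010), a pyrophosphatase induced by low phosphate, by 8.64 ± 0.31. FSD1 (AT4G25100), an iron superoxide dismutase, fell by 4.80 ± 0.24, from 607.1 to 21.7 CPM. The methionine sulfoxide reductase MSRB6 (AT4G04840) fell by 3.25 ± 0.16, the defensin-like gene PDF1.4 (AT1G19610) by 3.21 ± 0.22, the cytokinin response regulator ARR6 (AT5G62920) by 3.19 ± 0.16, OXS3 by 3.15 ± 0.12 and PDF1.3 by 3.05 ± 0.66. In the NIK1 module NIK2 rose by 0.41 ± 0.08, and RPL10B fell by 0.92 ± 0.11. NIK3 (-0.49 ± 0.10), RPL10A (-0.76 ± 0.08) and RPL10C (-0.52 ± 0.10) also fell but were at 0.39, 0.13 and 0.38 with total-count scaling. NIK1 (0.14 ± 0.10, adjusted p = 0.249) and NIG (0.11 ± 0.08, adjusted p = 0.236) did not pass. The list of 8 had a median of -0.19 against a mean of 0.20 (camera adjusted p = 0.651, downward; median 0.69 with total-count scaling and 0.11 with nuclear totals).

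Genes of translation and photosynthesis fell together in L1. Of 207 cytosolic ribosome genes 196 fell and 1 rose (median -0.99, adjusted p = 3.03e-35, adjusted p = 0.287 with an estimated correlation), with RPS21C at -1.73 ± 0.09. All 33 plastid ribosome genes fell (median -1.40, adjusted p = 4.33e-14, adjusted p = 0.413 with an estimated correlation), with PRPL35 at -1.96 ± 0.13. Translation factors fell in 19 of 30 cases and rose in 2 (median -0.28, adjusted p = 0.00105, adjusted p = 0.451 with an estimated correlation), or 0.61 with total-count scaling and 0.02 with nuclear totals; EF1BA1 fell by 1.51 ± 0.14. Ribosome biogenesis genes fell in 10 of 25 cases and rose in 2 (median -0.18, adjusted p = 0.102), or 0.71 and 0.12 with these scalings, with the helicase RH10 at -0.55 ± 0.09 and REIL1 at 0.52 ± 0.09. Nuclear photosynthesis genes fell in 51 of 54 cases (median -1.11, adjusted p = 1.19e-14, adjusted p = 0.413 with an estimated correlation). PSAN was at -2.23 ± 0.15 and PSBO2, of the oxygen-evolving complex, at -1.81 ± 0.14. By part, 32 of 33 photosystem and electron transport genes fell (median -1.18, adjusted p = 4.45e-11, adjusted p = 0.413 with an estimated correlation). Light-harvesting genes fell in 19 of 21 cases (median -1.02, adjusted p = 1.6e-07, adjusted p = 0.413 with an estimated correlation). Calvin cycle genes fell in 20 of 21 cases (median -1.29, adjusted p = 1.77e-08, adjusted p = 0.413 with an estimated correlation), with GAPA2 at -1.94 ± 0.14. In chlorophyll synthesis 15 of 22 fell and 3 rose (median -0.80, adjusted p = 0.00033, adjusted p = 0.492 with an estimated correlation), or 0.08 with total-count scaling. Root markers moved with these groups: 12 of 17 rose and 1 fell (median 2.42, adjusted p = 0.00176, adjusted p = 0.413 with an estimated correlation), with PHT1;1 at 2.87 ± 0.21 and the suberin gene GPAT5 at 3.23 ± 0.41.

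Pattern-triggered immunity genes rose in 21 of 30 cases in L1 and fell in 5 (median 0.79, adjusted p = 0.00169, adjusted p = 0.492 with an estimated correlation). WRKY33 was at 1.42 ± 0.17 and ERF104 at -1.59 ± 0.14. Salicylic acid genes rose in 19 of 28 cases and fell in 3 (median 0.84, adjusted p = 0.00231, adjusted p = 0.543 with an estimated correlation). The camalexin enzyme PAD3 was at 5.28 ± 0.51 and the regulator SARD1 at 1.3 ± 0.19. Genes of abscisic acid, osmotic and cold responses rose in 17 of 26 cases and none fell (median 0.86, adjusted p = 0.000283, adjusted p = 0.287 with an estimated correlation). NCED3, which makes the abscisic acid precursor under drought, rose by 4.32 ± 0.30 and the galactinol synthase GOLS2 by 4.96 ± 0.40. Jasmonate genes rose in 9 of 31 cases and fell in 4 (median 0.10, adjusted p = 0.378), with ERF1 at 4.38 ± 0.30 and LOX4 at 2.52 ± 0.31. Flavonoid genes rose in 6 of 17 cases and fell in 2 (median 0.53, adjusted p = 0.258), with the anthocyanin regulator PAP2 (MYB90) at 5.82 ± 0.43. Glucosinolate genes rose in 6 and fell in 10 of 20 cases (median -0.38, or 0.50 with total-count scaling; adjusted p = 0.198), with CYP79F1 at -1.92 ± 0.18.

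Of 14 iron deficiency genes 11 fell and 1 rose in L1 (median -2.01, adjusted p = 0.00198, adjusted p = 0.413 with an estimated correlation). The signalling peptide IMA1 was at -5.30 ± 0.52 and the phloem transporter OPT3 at -1.73 ± 0.13. All 23 cell cycle genes fell (median -1.06, adjusted p = 1.42e-09, adjusted p = 0.287 with an estimated correlation), with AUR2 at -2.19 ± 0.16. Flower genes fell in 3 of 4 cases (median -2.37, adjusted p = 0.0321, adjusted p = 0.301 with an estimated correlation), with SEP3 at -2.32 ± 0.12. The stomatal list had 4 of 9 higher and 1 lower (median 0.33, adjusted p = 0.756). Plastid-encoded transcripts fell in 68 of 74 cases (median -0.77, adjusted p = 8.64e-15, adjusted p = 0.413 with an estimated correlation), or 0.11 with total-count scaling, with ATCG00670 at -1.27 ± 0.10. Mitochondrion-encoded transcripts rose in 15 (range 7 to 16) and fell in 17 (range 11 to 18) of 75 cases (median -0.04, or 0.84 with total-count scaling; adjusted p = 0.571). Heat and unfolded protein genes (2 of 16 higher, 4 lower; median -0.11, or 0.78 with total-count scaling and 0.19 with nuclear totals; adjusted p = 0.607), morning clock genes (3 of 12 higher, 3 lower; median 0.08, camera downward, adjusted p = 0.92) and evening clock genes (2 of 9 higher, 4 lower; median -0.09, or 0.79 and 0.21; adjusted p = 0.571) did not pass. Among them the chaperone BIP3 was at 2.16 ± 0.35, ROF2 at -1.19 ± 0.14, RVE1 at -1.32 ± 0.18 and LUX at -0.82 ± 0.10. Of 18 genes beside LIMYB 6 rose and 7 fell (median -0.12 against a mean of 0.38, adjusted p = 0.92; median 0.77 with total-count scaling and 0.18 with nuclear totals), with ASA1 at 1.60 ± 0.22 and AT5G05900 at least 5.18-fold higher. In all, 12928 genes differed between L1 and Col-0, 6555 higher and 6373 lower. Camera passed 16 of the 27 lists, and 0 with an estimated correlation. Adjusted over the list alone, numbers were equal in 19 lists and within 1 in 24, with the largest change, 3, in the mitochondrion-encoded list.

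The comparison of L3 with Col-0 asks the same question in the other line, where LIMYB stood 3.93 ± 0.28 above Col-0. PAP25 (AT4G36350) was at least 308-fold higher, with 1583 counts against 0 over the groups, and PAP5 (AT1G52940) had 1797 counts against 2, a ratio of 524.3 with a 95% counting interval of 144.9 to 4332. PAP14 rose by 9.33, IPS1 by 9.19, PS2 by 8.19 ± 0.31 and NPC4 (AT3G03530), a phospholipase that frees phosphate from lipids, by 7.34 ± 0.27. FSD1 fell by 3.98 ± 0.23. MSRB6 fell by 3.49 ± 0.16, the inositol oxygenase MIOX2 (AT2G19800) by 3.37 ± 0.16, the proline dehydrogenase ERD5 (AT3G30775) by 3.35 ± 0.17, PDF1.4 by 3.27 ± 0.22 and BT1 (AT5G63160) by 3.23 ± 0.15. In the NIK1 module NIK2 rose by 0.89 ± 0.08. RPL10A fell by 1.08 ± 0.08, RPL10B by 1.2 ± 0.11 and RPL10C by 0.90 ± 0.10, and NIK3 was lower by -0.36 ± 0.10 but at 0.38 with total-count scaling. NIK1 (0.07 ± 0.10, adjusted p = 0.573) and NIG (0.01 ± 0.08, adjusted p = 0.9) did not pass. The list had a median of -0.18 and a mean of 0.17 (camera adjusted p = 0.51, downward; median 0.57 with total-count scaling and 0.16 with nuclear totals).

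In L3 201 of 207 cytosolic ribosome genes fell and none rose (median -1.16, adjusted p = 8.12e-43, adjusted p = 0.171 with an estimated correlation). RPL27B was at -1.79 ± 0.09. All 33 plastid ribosome genes fell (median -1.35, adjusted p = 4.07e-14, adjusted p = 0.355 with an estimated correlation). Translation factors fell in 26 of 30 cases (median -0.42, adjusted p = 2.37e-06, adjusted p = 0.355 with an estimated correlation), or 0.33 with total-count scaling, with the cap-binding protein EIF4E at -0.81 ± 0.09. Ribosome biogenesis genes fell in 20 of 25 cases and rose in 1 (median -0.34, adjusted p = 0.000676, adjusted p = 0.355 with an estimated correlation), or 0.40 with total-count scaling. Nuclear photosynthesis genes fell in 48 of 54 cases (median -0.91, adjusted p = 1.09e-11, adjusted p = 0.416 with an estimated correlation), with PSAN at -2.00 ± 0.14. By part, 30 of 33 photosystem and electron transport genes fell (median -0.98, adjusted p = 7.96e-09, adjusted p = 0.416 with an estimated correlation), as did 18 of 21 light-harvesting genes (median -0.88, adjusted p = 3.17e-06, adjusted p = 0.416 with an estimated correlation). Calvin cycle genes fell in 20 of 21 cases (median -1.08, adjusted p = 1.46e-07, adjusted p = 0.416 with an estimated correlation). Chlorophyll genes fell in 15 of 22 cases and rose in 3 (median -0.76, adjusted p = 0.000638, adjusted p = 0.471 with an estimated correlation). Root markers moved with these groups, 12 of 17 higher and none lower (median 2.17, adjusted p = 0.00148, adjusted p = 0.355 with an estimated correlation).

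Genes of abscisic acid, osmotic and cold responses rose in 21 of 26 cases in L3 and none fell (median 1.34, adjusted p = 5.14e-07, adjusted p = 0.111 with an estimated correlation). RD29A, a marker of cold and drought, rose by 2.60 ± 0.11 and GOLS2 by 6.02 ± 0.38. Salicylic acid genes rose in 19 of 28 cases and fell in 1 (median 0.96, adjusted p = 0.000638, adjusted p = 0.456 with an estimated correlation). The wall-associated kinase WAK1 was at 2.29 ± 0.20 and WRKY70 at 1.73 ± 0.23. Flavonoid genes rose in 11 of 17 cases and fell in 2 (median 1.70, adjusted p = 0.00728, adjusted p = 0.416 with an estimated correlation), with PAP2 (MYB90) at 6.47 ± 0.42. Pattern-triggered immunity genes rose in 18 and fell in 8 of 30 cases (median 0.52, adjusted p = 0.0924), with CPK28 at 0.71 ± 0.09 and CMPG1 at -1.67 ± 0.20. Jasmonate genes rose in 7 (range 4 to 9) and fell in 6 (range 3 to 9) of 31 cases (median 0.01, adjusted p = 0.793), with ERF1 at 3.76 ± 0.30 and JAZ9 at -1.18 ± 0.27. Glucosinolate genes rose in 5 and fell in 11 of 20 cases (median -0.44, or 0.30 with total-count scaling; adjusted p = 0.131), with FMOGSOX1 at -1.66 ± 0.17.

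Iron deficiency genes fell in 11 of 14 cases in L3 and 1 rose (median -2.58, adjusted p = 0.000502, adjusted p = 0.355 with an estimated correlation). IMA1 was at -6.99 ± 0.60 and OPT3 at -2.00 ± 0.13, and IMA3 had 2 counts against 187, a ratio of 0.00624 with a 95% counting interval of 0.00075 to 0.0229. All 23 cell cycle genes fell (median -1.07, adjusted p = 7.76e-10, adjusted p = 0.199 with an estimated correlation), with AUR2 at -2.23 ± 0.15. Flower genes fell in 3 of 4 cases (median -2.52, adjusted p = 0.00657, adjusted p = 0.171 with an estimated correlation), with SEP3 at -2.43 ± 0.12. The stomatal list had 4 of 9 higher and 2 lower (median 0.46, adjusted p = 0.707). Plastid-encoded transcripts fell in 68 of 74 cases (median -0.78, adjusted p = 6.72e-14, adjusted p = 0.355 with an estimated correlation). Mitochondrion-encoded transcripts rose in 11 (range 7 to 12) and fell in 17 of 75 cases (median -0.06, or 0.68 with total-count scaling; adjusted p = 0.477). Heat and unfolded protein genes (1 of 16 higher, 7 lower, range 4 to 7; median -0.35, or 0.40 with total-count scaling; adjusted p = 0.22), morning clock genes (4 of 12 higher, 2 lower; median 0.28; adjusted p = 0.51) and evening clock genes (3 of 9 higher, 4 lower; median -0.06, or 0.68 with total-count scaling and 0.27 with nuclear totals; adjusted p = 0.596) did not pass, with BIP3 at 1.92 ± 0.35, HSP18.2 at -1.99 ± 0.35 and LUX at -0.95 ± 0.10. Of 18 genes beside LIMYB 6 rose and 6 fell (median -0.12 against a mean of 0.25, adjusted p = 0.711; median 0.62 with total-count scaling and 0.21 with nuclear totals). In all, 12698 genes differed between L3 and Col-0, 6373 higher and 6325 lower. Camera passed 17 of the 27 lists, and 0 with an estimated correlation. Adjusted over the list alone, numbers were equal in 21 lists and within 1 in 26, with the largest change, 2, in the salicylic acid list.

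Both lines changed in much the same way against Col-0. Of genes called in both, 11090 went the same way, 5525 higher and 5565 lower, and 13 opposite ways. Independent lists of these sizes would share 1964 higher and 1895 lower genes. Unchanged simulated groups shared 0 in 20 simulations, but cannot show what shared controls add to changed groups. Across genes, which are not independent replicates, the fold changes of the lines correlated with r = 0.922 (simulated 0.543) and a covariance of 1.33 (simulated 0.0359). The 3 Col-0 libraries cannot be split with 2 in each part, so they may give part of the excess.

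**Figure D3:**
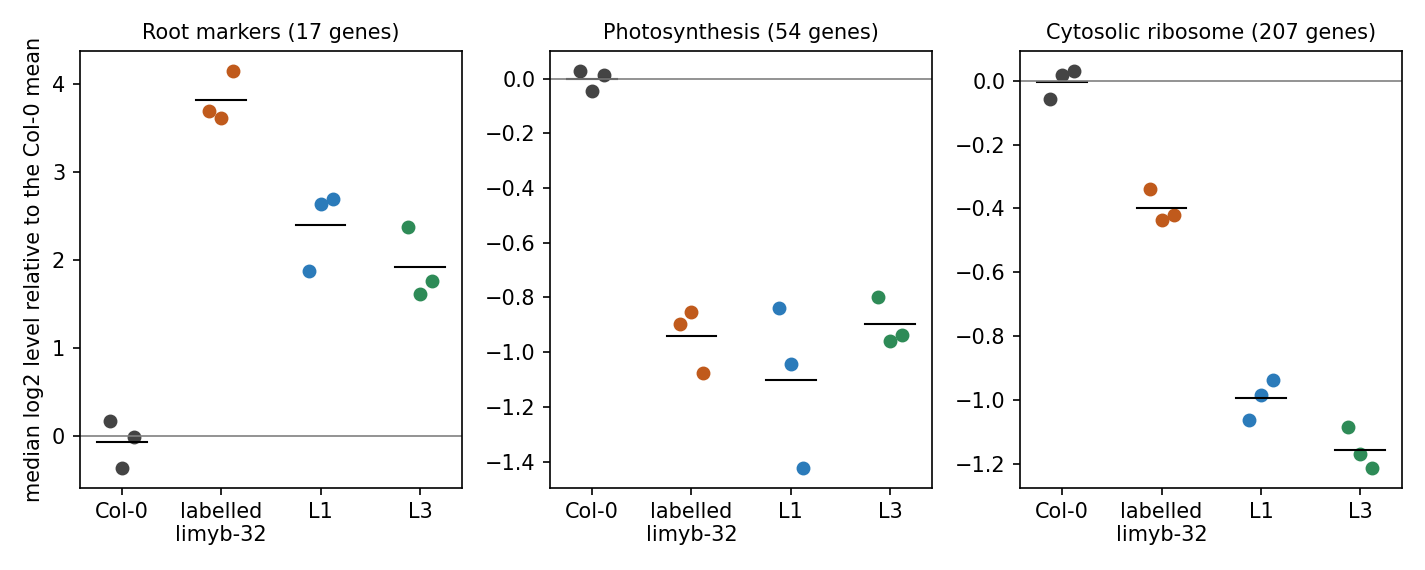
Median log2 level of root markers (17 genes), nuclear photosynthesis genes (54) and cytosolic ribosome genes (207) in each library relative to the Col-0 mean; points are libraries and lines group means. Root markers lie between 3.61 and 4.14 in the libraries labelled limyb-32 and between 1.61 and 2.69 in the lines, photosynthesis lies between -1.42 and -0.80 in all 3 groups, and the ribosome lies between -0.44 and -0.34 in the libraries labelled limyb-32 and between -1.21 and -0.94 in the lines; the ribosomal median of the libraries labelled limyb-32 turns positive (0.51) with total-count scaling.

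The comparison of L1 with the libraries labelled limyb-32 asks what the construct changed in its own background, with LIMYB higher in L1 by 2.52 ± 0.26. CYP82C2 was higher by 11.18 ± 1.74, the peroxidase PRX52 (AT5G05340) by 6.78 ± 0.48, the glucosidase DIN2 (AT3G60140), induced by darkness and sugar starvation, by 6.10 ± 0.51 and ABCG40 (AT1G15520), an importer of abscisic acid, by 6.09 ± 0.61. The transporter ABCA10 (AT5G61740) fell by 4.14 ± 0.26, the membrane protein PCR1 (AT1G14880) by 4.07 ± 0.71, the acetyl-CoA carboxylase ACC2 (AT1G36180) by 4.05 ± 0.22 and the glutathione transferase GSTF14 (AT1G49860) by 3.96 ± 0.42. In the NIK1 module NIK1 rose by 0.36 ± 0.10, NIG by 0.28 ± 0.08 and RPL10C by 0.26 ± 0.10 (adjusted p = 0.0397, lost when any of 6 single libraries was left out). RPL10A fell by 0.45 ± 0.08 and RPL10B by 0.69 ± 0.11, while NIK2 (0.14 ± 0.07, adjusted p = 0.133) and NIK3 (0.10 ± 0.10, adjusted p = 0.386) did not pass. The list had a median of 0.20 (adjusted p = 0.402).

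Most genes of the cytosolic ribosome, of its assembly and of translation factors fell from the level in the libraries labelled limyb-32. Of 207 cytosolic ribosome genes 201 fell and 2 rose (median -0.60, adjusted p = 8.36e-31, adjusted p = 0.24 with an estimated correlation). The stalk protein RPP2C was at -4.19 ± 0.29. Translation factors fell in 23 of 30 cases and rose in 1 (median -0.37, adjusted p = 6.05e-06, adjusted p = 0.309 with an estimated correlation), with EF1BA1 at -1.94 ± 0.14. Ribosome biogenesis genes fell in 20 of 25 cases and rose in 2 (median -0.54, adjusted p = 4.15e-06, adjusted p = 0.24 with an estimated correlation). Plastid ribosome genes did not pass (1 of 33 lower, range 1 to 7, PRPL10 at -0.39 ± 0.10; median -0.10, adjusted p = 0.225). Nuclear photosynthesis genes stayed near the level of the libraries labelled limyb-32, with 9 of 54 lower (range 6 to 21) and 1 higher (range 0 to 7; median -0.08, adjusted p = 0.23). Without L1 replicate 1 their median was -0.23 (adjusted p = 0.000819) and without L1 replicate 3 it was 0.06. LHCB1.1 fell by 0.51 ± 0.11 and PSBO2 by 0.62 ± 0.14, and PSAD2 was at 0.36 ± 0.14 (adjusted p = 0.0446, lost when any of 10 single libraries was left out). The light-harvesting part (6 of 21 lower, range 3 to 9, median -0.11, adjusted p = 0.126), the photosystem part (3 of 33 lower, range 3 to 12, 1 higher, range 0 to 7, median -0.02, adjusted p = 0.614) and the Calvin cycle (7 of 21 lower, range 7 to 11, 1 higher, median -0.27, adjusted p = 0.11) did not pass, with RBCS2B at 1.15 ± 0.19 and Rubisco activase RCA at -1.04 ± 0.15. In chlorophyll synthesis 3 of 22 rose and 6 fell, with a median of -0.14 against a mean of 0.14 (adjusted p = 0.556); PORA, a protochlorophyllide reductase of dark-grown tissue, rose by 5.02 ± 0.29 and the chloroplast regulator GLK1 by 0.96 ± 0.09.

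Pattern-triggered immunity genes rose in 28 of 30 cases in L1 (median 0.91, adjusted p = 9.11e-10, adjusted p = 0.24 with an estimated correlation). WRKY40 was at 3.62 ± 0.29. Jasmonate genes rose in 25 of 31 cases and fell in 1 (median 1.48, adjusted p = 4.54e-07, adjusted p = 0.472 with an estimated correlation). ERF1 was at 3.91 ± 0.27 and LOX4 at 2.58 ± 0.30. Genes of abscisic acid, osmotic and cold responses rose in 17 of 26 cases and fell in 3 (median 0.72, adjusted p = 8.69e-05, adjusted p = 0.24 with an estimated correlation). NCED3 was at 3.92 ± 0.27, RAB18 at 2.95 ± 0.23 and RD22 at -1.37 ± 0.10. Salicylic acid genes went both ways (11 of 28 higher, range 6 to 13, 4 lower; median 0.19, adjusted p = 0.331), with PAD3 at 3.51 ± 0.44 and the glucanase PR2 at -2.88 ± 0.30. Stomatal genes rose in 9 of 9 cases (median 1, adjusted p = 4.65e-05, adjusted p = 0.24 with an estimated correlation), with FAMA at 1.14 ± 0.11. Morning clock genes rose in 5 of 12 cases (median 0.30, adjusted p = 0.0233, adjusted p = 0.441 with an estimated correlation), with RVE1 at 0.97 ± 0.19, and evening genes rose in 5 and fell in 1 of 9 (median 0.29, adjusted p = 0.223).

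Glucosinolate genes fell in 15 of 20 cases in L1 and 2 rose (median -1.13, adjusted p = 1.39e-05, adjusted p = 0.24 with an estimated correlation). CYP79F1 was at -2.38 ± 0.18. Root markers fell in 14 of 17 cases (median -1.97, adjusted p = 0.0001, adjusted p = 0.24 with an estimated correlation), with COBL9 at -2.55 ± 0.31; the iron transporter IRT1 was at least 271-fold lower, with 0 counts against 1072. Cell cycle genes fell in 12 of 23 cases (median -0.41, adjusted p = 0.00082, adjusted p = 0.441 with an estimated correlation), with CYCB1;1 at -1.82 ± 0.11. Iron deficiency genes fell in 8 (range 5 to 10) and rose in 2 of 14 cases (median -1.66, adjusted p = 0.11). Flavonoid genes fell in 7 and rose in 4 of 17 cases (median -0.04, adjusted p = 0.424), with CHS at -2.37 ± 0.23 and PAP2 (MYB90) at 3.12 ± 0.30. Mitochondrion-encoded transcripts fell in 69 of 75 cases (median -1.14, adjusted p = 6.29e-19, adjusted p = 0.24 with an estimated correlation), with ATMG01350 at -1.65 ± 0.10. Plastid-encoded transcripts fell in 36 and rose in 10 of 74 cases (median -0.28, adjusted p = 0.000362, adjusted p = 0.718 with an estimated correlation), with ATCG00170 at -1.89 ± 0.10. Flower genes (1 of 4 lower, SEP3 at -0.91 ± 0.12; median -0.65, adjusted p = 0.267), heat and unfolded protein genes (3 of 16 higher, 4 lower; median 0.08, adjusted p = 0.947) and genes beside LIMYB (4 of 18 higher, 4 lower; median 0.02, or -0.01 with total-count scaling and with nuclear totals, and mean -0.10; adjusted p = 0.908) did not pass. In all, 10742 genes differed between L1 and the libraries labelled limyb-32, 5233 higher and 5509 lower. Camera passed 13 of the 27 lists, and 0 with an estimated correlation. Adjusted over the list alone, numbers were equal in 13 lists and within 1 in 24, with the largest change, 3, in the nuclear photosynthesis list.

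The comparison of L3 with the libraries labelled limyb-32 repeats the question in the other line, with LIMYB higher in L3 by 2.80 ± 0.26. CYP82C2 was higher by 7.77 ± 1.77, a value carried by replicate spread (13.0 CPM ± 21.2 SD) that was 3.79 without L3 replicate 1. The glucosidase BGLU28 (AT2G44460), linked to sulfur supply, rose by 6.14 ± 0.41, PRX52 by 5.36 ± 0.46 and CYP81D11 (AT3G28740), which responds to jasmonate and foreign compounds, by 4.76 ± 0.30. The transcription factors NAC044 (AT3G01600), linked to DNA damage, and NAC103 (AT5G64060), linked to the unfolded protein response, fell by 4.77 ± 0.31 and 3.79 ± 0.20, ABCA10 by 4.16 ± 0.26 and ACC2 by 4.14 ± 0.22. In the NIK1 module NIK2 rose by 0.61 ± 0.07 and NIK1 by 0.29 ± 0.10 (adjusted p = 0.031, lost when any of 4 single libraries was left out). RPL10A fell by 0.77 ± 0.08 and RPL10B by 0.98 ± 0.11, while NIK3 (0.23 ± 0.10, adjusted p = 0.064), NIG (0.19 ± 0.08, adjusted p = 0.0535) and RPL10C (-0.13 ± 0.10, adjusted p = 0.309) did not pass. The list had a median of 0.21 (adjusted p = 0.599).

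Of 207 cytosolic ribosome genes 204 fell and 1 rose in L3 against the libraries labelled limyb-32 (median -0.76, adjusted p = 9.12e-41, adjusted p = 0.166 with an estimated correlation). RPP2C was at -3.92 ± 0.27 and RPL19B at -1.13 ± 0.07. Translation factors fell in 26 of 30 cases (median -0.49, adjusted p = 2.7e-09, adjusted p = 0.199 with an estimated correlation). Ribosome biogenesis genes fell in 21 of 25 cases (median -0.81, adjusted p = 2.7e-09, adjusted p = 0.157 with an estimated correlation), with NOP58_1 at -1.12 ± 0.09. Plastid ribosome genes did not pass (0 of 33 called, lower range 0 to 4; median -0.09, adjusted p = 0.477). Nuclear photosynthesis genes were higher in 10 of 54 cases (range 5 to 8) and lower in 3 (median 0.11, or -0.07 with total-count scaling; adjusted p = 0.22), with PSAD2 at 0.58 ± 0.14 and LHCB1.1 at -0.64 ± 0.11. The light-harvesting part (2 of 21 higher, 2 lower; median 0.05, or -0.13 with total-count scaling, against a mean of -0.01; adjusted p = 0.998), the photosystem part (8 of 33 higher, range 4 to 7, 1 lower; median 0.19, adjusted p = 0.0818) and the Calvin cycle (2 of 21 higher, 7 lower; median -0.12, adjusted p = 0.641) did not pass, with RBCS2B at 1.29 ± 0.19 and RCA at -0.76 ± 0.15. In chlorophyll synthesis 3 of 22 rose and 7 (range 3 to 8) fell, and the median (-0.10) differed in sign from the mean (0.20) and the camera direction (adjusted p = 0.998). PORA was at 4.53 ± 0.29 and GLK1 at 1.14 ± 0.09.

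Genes of abscisic acid, osmotic and cold responses rose in 21 of 26 cases in L3 and fell in 2 (median 1.03, adjusted p = 5.81e-08, adjusted p = 0.0684 with an estimated correlation). RAB18, a dehydrin, was at 4.12 ± 0.23. Jasmonate genes rose in 22 of 31 cases (median 1.1, adjusted p = 1.44e-05, adjusted p = 0.539 with an estimated correlation), with VSP1 at 3.88 ± 0.49 and ERF1 at 3.29 ± 0.27. Pattern-triggered immunity genes rose in 19 of 30 cases and fell in 1 (median 0.52, adjusted p = 3.46e-05, adjusted p = 0.408 with an estimated correlation). Stomatal genes rose in 8 of 9 cases (median 1.22, adjusted p = 3.46e-05, adjusted p = 0.199 with an estimated correlation), and morning clock genes in 10 of 12 (median 0.50, adjusted p = 0.000815, adjusted p = 0.208 with an estimated correlation). Salicylic acid genes (9 of 28 higher, 3 lower; median 0.18, adjusted p = 0.252), flavonoid genes (8 of 17 higher, range 5 to 8, 5 lower; median 0.71, adjusted p = 0.599) and evening clock genes (4 of 9 higher, 2 lower; median 0.26, adjusted p = 0.22) did not pass as lists. Examples are WRKY70 at 1.44 ± 0.22 and PAP2 (MYB90) at 3.78 ± 0.30.

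Glucosinolate genes fell in 16 of 20 cases in L3 and 1 rose (median -1.2, adjusted p = 3.62e-06, adjusted p = 0.199 with an estimated correlation). Root markers fell in 16 of 17 cases (median -1.86, adjusted p = 2.17e-05, adjusted p = 0.199 with an estimated correlation). Cell cycle genes fell in 12 of 23 cases (median -0.36, adjusted p = 0.00096, adjusted p = 0.415 with an estimated correlation). Iron deficiency genes fell in 9 of 14 cases (median -1.88, adjusted p = 0.0164, adjusted p = 0.509 with an estimated correlation), with IMA1 at -4.68 ± 0.65. Mitochondrion-encoded transcripts fell in 68 of 75 cases (median -1.25, adjusted p = 8.29e-20, adjusted p = 0.199 with an estimated correlation). Plastid-encoded transcripts fell in 36 and rose in 17 (range 11 to 13) of 74 cases (median -0.31, adjusted p = 0.00953, adjusted p = 0.836 with an estimated correlation). Flower genes (1 of 4 lower, SEP3 at -1.02 ± 0.12; median -0.88, adjusted p = 0.1), heat and unfolded protein genes (3 of 16 higher, 5 lower; median -0.05, adjusted p = 0.599) and genes beside LIMYB (3 of 18 higher, 4 lower; median -0.04, adjusted p = 0.602), with UGT76C2 at -1.48 ± 0.14, did not pass. In all, 10424 genes differed between L3 and the libraries labelled limyb-32, 5033 higher and 5391 lower. Camera passed 14 of the 27 lists, and 0 with an estimated correlation. Adjusted over the list alone, numbers were equal in 14 lists and within 1 in 23, with no change over 2.

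Of the 12408 genes that differed between the libraries labelled limyb-32 and Col-0, 4147 differed in the opposite direction in both lines against those libraries. Of these 4147, 2451 were higher and 1696 lower in the libraries labelled limyb-32, and 1818 were not called against Col-0 in either L1 or L3. For single lines the number was 4745 in L1 (independent lists 1667 and 1469; largest of 20 simulations 1) and 4948 in L3 (independent lists 1632 and 1413; largest simulated 0). In the same direction 2132 genes were called in L1 and 1885 in L3. With the sign reversed, fold changes correlated across genes with r = 0.399 in L1 (simulated 0.454) and r = 0.493 in L3 (simulated 0.462), and covariances of 0.512 (simulated 0.028) and 0.567 (simulated 0.0279). These comparisons share the libraries labelled limyb-32 with opposite sign, which may give part of the excess. Simulated groups were all unchanged. The number called the same way against Col-0 in the libraries labelled limyb-32, L1 and L3 was 7393, 3469 higher and 3924 lower; these comparisons share the Col-0 libraries. By pairs, limyb-32 shared 8113 calls with L1 (independent lists 1984 and 1789, simulated 0; r = 0.677, simulated 0.547) and 8038 with L3 (independent lists 1929 and 1775, simulated 0; r = 0.716, simulated 0.558). A further 3122 genes were called the same way in both lines and not called in the libraries labelled limyb-32.

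The comparison of L3 with L1 asks whether the lines, which carry the same construct, differ. LIMYB did not pass (0.28 ± 0.24, adjusted p = 0.627). LURP1 (AT2G14560), a pathogen-response gene, rose by 2.92 ± 0.38, TBL36 (AT3G54260), a cell wall acetylation family member, by 1.82 ± 0.30, and the drought-repressed gene DR4 (AT1G73330) by 1.78 ± 0.16. The cell death regulator ACD6 (AT4G14400) rose by 2.23 ± 0.43, a call lost without L3 replicate 1 (1.79, adjusted p = 0.0547). NHL10 (AT2G35980), an immune marker, fell by 3.71 ± 0.57, PXMT1 by 3.58 ± 0.41 and the glucosidase BGLU27 (AT3G60120) by 3.25 ± 0.56. CYP82C3 (AT4G31950) fell by 4.09 ± 0.85, but not without L1 replicate 3 (-2.90), L3 replicate 2 (-3.55) or L3 replicate 3 (-3.55). In the NIK1 module NIK2 rose by 0.47 ± 0.07, and RPL10A (-0.32 ± 0.08, adjusted p = 0.0424) and RPL10C (-0.39 ± 0.10, adjusted p = 0.0464) passed narrowly and lost the call when any of 8 and of 10 single libraries was left out. RPL10B (-0.29 ± 0.11, adjusted p = 0.209), NIK1 (-0.07 ± 0.10, adjusted p = 0.792), NIK3 (0.12 ± 0.10, adjusted p = 0.579) and NIG (-0.10 ± 0.08, adjusted p = 0.584) did not pass, nor did the list (median -0.08, adjusted p = 0.452).

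Pattern-triggered immunity genes fell in 10 of 30 cases in L3 against L1 and 1 rose, or 16 and 1 adjusted over the list alone (median -0.46, adjusted p = 1.85e-07, adjusted p = 0.53 with an estimated correlation). The calmodulin-like CML37 was at -2.68 ± 0.45 and PROPEP3, precursor of a danger peptide, at -2.90 ± 0.52. Jasmonate genes fell in 2 of 31 cases (median -0.47, adjusted p = 0.0117, adjusted p = 0.799 with an estimated correlation), CYP94B3 at -2.60 ± 0.34 and LOX4 at -1.41 ± 0.29 (lost with any of 4 libraries left out). Genes of abscisic acid, osmotic and cold responses rose in 10 of 26 cases (median 0.23, adjusted p = 1.83e-05, adjusted p = 0.232 with an estimated correlation). KIN2 was at 1.19 ± 0.14 and RD29A at 1.04 ± 0.10. Flavonoid genes rose in 1 of 17 cases, CHS at 1.42 ± 0.23, and in 9 adjusted over the list alone (median 0.76, adjusted p = 1.49e-05, adjusted p = 0.53 with an estimated correlation). Salicylic acid genes split, 3 of 28 higher and 3 lower (range 0 to 7), or 6 and 6 adjusted over the list alone (median -0.08 with an upward camera direction, adjusted p = 0.994). PR2 was at 2.21 ± 0.31, WAK1 at 1.56 ± 0.19 and PAD3 at -2.17 ± 0.41 (lost with either of 2 libraries left out). Ribosomal genes fell in 7 of 207 cases (median -0.15, adjusted p = 1.36e-16, adjusted p = 0.53 with an estimated correlation), with RPL19B at -0.40 ± 0.07. With single libraries left out, the number lower ran from 5 to 18 for pattern-triggered immunity, from 1 to 9 for jasmonate and from 1 to 11 for the ribosome, each highest without L1 replicate 1. For abscisic acid, osmotic and cold responses the number higher ran from 5 to 10, with 5 without L1 replicate 3, L3 replicate 1 or L3 replicate 3. The jasmonate median was 0.11 without L1 replicate 3. Translation factors (median -0.11, adjusted p = 0.000567, adjusted p = 0.628 with an estimated correlation) had EIF6A at -0.70 ± 0.07 and EF1BA1 at 0.66 ± 0.14 (lost when any of 4 single libraries was left out) as the members called, and ribosome biogenesis (median -0.19, adjusted p = 7.18e-07, adjusted p = 0.342 with an estimated correlation) had REIL2 at -0.32 ± 0.08 (lost with any of 6 left out).

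Photosynthesis lists lay slightly higher in L3 than in L1, and the number called depended on L1 replicate 1. Without it 15 of 54 nuclear photosynthesis genes were higher, 10 of 33 for photosystems, 5 of 21 for light harvesting and 9 of 21 for the Calvin cycle, against 1, 0, 1 and 0 with it. The medians were 0.20 for all 54 nuclear genes (adjusted p = 5.04e-08), 0.21 for photosystems and electron transport (adjusted p = 4.2e-07), 0.18 for light harvesting (adjusted p = 0.00106) and 0.17 for the Calvin cycle (adjusted p = 0.000716), each with adjusted p = 0.628 with an estimated correlation. LHCB4.3 at 0.61 ± 0.13 was the member called, lost when any of 4 single libraries was left out, and without L1 replicate 3 the median of the 54 genes was 0.06 (adjusted p = 0.136). Morning clock genes (0 of 12 called; median 0.17, adjusted p = 0.0135, adjusted p = 0.628 with an estimated correlation), iron deficiency genes (0 of 14; median -0.58, adjusted p = 0.0319, adjusted p = 0.628 with an estimated correlation) and plastid-encoded transcripts (1 of 74, range 0 to 7, ATCG00420 at 0.39 ± 0.10, lost with RLE factors and when any of 11 single libraries was left out; median 0.06, or -0.07 with total-count scaling, adjusted p = 0.0117, adjusted p = 0.842 with an estimated correlation) passed camera with small medians or few calls. The other lists did not pass. These were plastid ribosome (median 0.02, or -0.11 with total-count scaling; adjusted p = 0.327), chlorophyll synthesis (0.06, or -0.07; adjusted p = 0.156), glucosinolates (higher range 0 to 4; 0.04, or -0.10; adjusted p = 0.836; CYP79B2 at -1.67 ± 0.30), stomatal genes (0.04, or -0.10; adjusted p = 0.976), root markers (-0.25 against a mean of 0.10; adjusted p = 0.471), flower genes (-0.16; adjusted p = 0.327), and heat and unfolded protein genes (-0.29; adjusted p = 0.156). Cell cycle genes (-0.01, or 0.02 with nuclear totals; adjusted p = 0.925), evening clock genes (-7.14e-06, or 0.03 with nuclear totals; adjusted p = 0.994), mitochondrion-encoded transcripts (-0.02; adjusted p = 0.818) and genes beside LIMYB (-0.04; adjusted p = 0.327; ASA1 at -0.88 ± 0.22, but -0.51 without L1 replicate 3, and lost when any of 10 single libraries was left out) did not pass either. In all, 774 genes differed between L3 and L1, 231 higher and 543 lower, a number that fell to 160 with only the 6 libraries compared and ranged from 336 to 1965 when single libraries were left out. Camera passed 14 of the 27 lists, and 0 with an estimated correlation. Adjusted over the list alone, numbers were equal in 18 lists and within 1 in 23.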

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

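The difference between the lines was a planned comparison, and of the values here only total-count scaling of a list was chosen after results had been seen. With 3 libraries in a group, no single library can be shown to stand apart by a test. L1 and L3 carry the same construct, yet 774 genes differed between them in the direct test. At the level of lists, camera gave differences between the lines with medians of -0.15 for the cytosolic ribosome, -0.109 for translation factors, -0.189 for ribosome biogenesis, 0.179 for light harvesting, 0.211 for photosystems and electron transport, 0.195 for nuclear photosynthesis and 0.167 for the Calvin cycle. The medians were -0.461 for pattern-triggered immunity, -0.47 for jasmonate, 0.232 for abscisic acid, osmotic and cold responses, 0.171 for morning clock genes, 0.76 for flavonoids, -0.583 for iron deficiency and 0.0613 for plastid-encoded transcripts, the last turning negative (-0.07) with total-count scaling. None of these lists passed with an estimated correlation. L1 replicate 1 correlated best with L3 replicate 2, and without it 1965 genes differed; L1 replicates 1 and 3 were the replicates furthest apart (chi-square per degree of freedom 112, the next being 40.3). Without the shallower L1 replicate 2, 387 genes still differed. Lines of independent insertion and different plant pools are confounded with the line, and no explanation of the difference was tested.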

How the results depend on the processing

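Total-count and nuclear-total scaling of the photosynthesis and cytosolic ribosome lists, and nuclear-total scaling of the gene counts, were chosen after the data had been seen. The numbers of genes called against Col-0 and against limyb-32 stayed within 1.5 times under every alternative except the 2-fold minimum, which left 4312 genes for limyb-32, 4486 for L1 and 4088 for L3 against Col-0, 3394 for L1 and 3064 for L3 against limyb-32, and 423 for L3 against L1. The 774 genes of L3 against L1 (231 higher, 543 lower) became 1305 (137 and 1168) with total-count scaling, 1263 (384 and 879) with DESeq2, 441 with a filter of 5 CPM and 160 (72 and 88) with only the 6 libraries compared. Without single libraries they were 1965, 387 and 411 (L1 replicates 1, 2 and 3) and 369, 336 and 429 (L3 replicates 1, 2 and 3). With an estimated correlation the cytosolic ribosome list lost its call in limyb-32 (-0.42, adjusted p = 0.347), L1 (-0.99, 0.287) and L3 (-1.16, 0.171) against Col-0, in L1 (-0.60, 0.24) and L3 (-0.76, 0.166) against limyb-32, and in L3 against L1 (-0.15, 0.53; with fry 0.0747). Nuclear photosynthesis lost it in limyb-32 (-0.96, 0.347), L1 (-1.11, 0.413) and L3 (-0.91, 0.416) against Col-0 and in L3 against L1 (0.20, 0.628; with fry 0.362). With total-count scaling the ribosomal median reversed in limyb-32 against Col-0 (0.51, adjusted p = 0.326) and the photosynthesis median in L3 against limyb-32 (-0.0674, adjusted p = 0.484). The photosynthesis median of L1 against limyb-32 ran from -0.23 without L1 replicate 1 (adjusted p = 0.000819) to 0.0574 without L1 replicate 3 (adjusted p = 0.538), and that of L3 against L1 from 0.0559 without L1 replicate 3 (adjusted p = 0.136) to 0.36 without L1 replicate 1. Values near 0 changed sign when single libraries were left out. These were NIK1 in L3 against Col-0 (-0.0204 without L3 replicate 2; up to 0.15), NIG there (-0.0279 without L3 replicate 2 and -0.00187 without L3 replicate 3; up to 0.0715), NIK3 in L1 against limyb-32 (-0.00432 without L1 replicate 1; up to 0.22, adjusted p = 0.0296, without L1 replicate 3) and NIK1 in L3 against L1 (-0.18 to 0.000338, the latter without L3 replicate 3). The evening clock list of L3 against L1 changed sign with the replicate block (0.00607). The block also took the call from the iron list in limyb-32 (-1.02, adjusted p = 0.053) and from RPL10A in L3 against L1 (-0.32, adjusted p = 0.0521), and gave it to flower markers (-0.87, adjusted p = 0.0432), NIG (adjusted p = 0.0408) and NIK3 (adjusted p = 0.0498) in L3 against limyb-32 and to NIG in limyb-32 against Col-0 (adjusted p = 0.0461). Of the values of named genes with a library left out, 4196 kept direction and side of the threshold, 85 lost the call and 10 gained it, with most of the losses in L3 against L1. In L3 against L1 EF1BA1, REIL2, LHCB4.3, PAD3, LOX4, ATCG00420 (also with RLE factors, adjusted p = 0.0512) and ASA1 lost it without at least 2 of the 6 libraries compared, as did LUX in L3 against limyb-32 (-0.25 without L3 replicate 3). With DESeq2 353 values of named genes kept both and 1 gained the call (NIG in L3 against limyb-32, 0.18, adjusted p = 0.0454); DESeq2 gave no adjusted p for CYP82C2 and CYP82C3. The cause of these changes was not tested, except that fewer libraries leave less power.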

Other observations

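Chosen after results had been seen were the 4 added lists (phosphate starvation, a further root list, mitochondrial stress, unfolded protein) and the tests of mixed or mislabelled libraries, of leaf RNA, of plastid share, of matched genes in limyb-32 and of lists against draws of matched genes, and of root RNA behind the phosphate genes; what would count for the mixing test was changed, and the mislabelling test narrowed, after their values were seen. Genes known to rise under phosphate starvation rose against Col-0 in 85% of 20 measured cases in the libraries labelled limyb-32 (median 1.94; adjusted p = 0.352 with an estimated correlation) and in 95% in L1 (median 3.15; adjusted p = 0.265 with an estimated correlation) and in L3 (median 3.12; adjusted p = 0.299 with an estimated correlation). MGD3, which makes galactolipids that replace phospholipids, was at 5.40, 6.88 and 7.07 in limyb-32, L1 and L3, and SPX3, a regulator of phosphate signalling, at 3.82, 6.57 and 6.22. The list was also higher in both lines than in limyb-32 (lower median 1.26; adjusted p = 0.323 and 0.324 with an estimated correlation) while root markers were lower there, which root RNA alone would not give. A shortage of phosphate in the plants is a candidate explanation; the labels record no phosphate supply.

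Mitochondrial stress genes, which respond to impaired respiration, differed between the lines. All 10 rose in L1 against Col-0 (median 1.76; adjusted p = 0.247 with an estimated correlation). In L3 6 rose and 1 fell and the list did not pass (median 0.42, adjusted p = 0.251; 3 rose without L3 replicate 1), and 9 of 10 were lower in L3 than in L1 (median -1.58, adjusted p = 9.81e-18; adjusted p = 0.0288 with an estimated correlation). In limyb-32, 50% of these genes rose, which left such stress open for its higher mitochondrion-encoded transcripts. Root markers were highest there too, and root RNA was not tested. NAC103 stood at 6.92 CPM in limyb-32 and 0.499 CPM in L3. Of 15 unfolded protein genes 60% were higher in limyb-32, just at the share set for that explanation. The list did not pass (adjusted p = 0.181, or 0.823 with an estimated correlation).

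LIMYB was higher in the libraries labelled limyb-32 than in Col-0. Reads from a near-identical copy do not explain it, since 0 other loci matched a read length at 90% identity, and 6 of the 6 libraries labelled limyb-32 or Col-0 correlated best with a library of their own group, against a single mislabelled library among them (11 of 12 over all libraries, the exception being L1 replicate 1, closest to L3 replicate 2). Mixing with RNA or reads of a LIMYB line would need a fraction of 0.178, 0.0881 and 0.0106 in replicates 1, 2 and 3 if the rest held the LIMYB level of Col-0, or 23.7, 15.4 and 8.17% if it held none. Of 4101 genes abundant in the lines, 2 (BGLU28 at 0.899% and PRX52 at 4.91%), 4 and 0 lay under 0.5 of the former, too few to decide. A label exchanged for the whole group, or transcription driven by the insertion, could also give this level, and neither was tested.

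Photosynthesis and ribosomal genes were lower in the lines than in Col-0. A smaller share of leaf RNA is not the whole source for photosynthesis, since root markers fell from limyb-32 to the lines while the higher photosynthesis median of the lines against limyb-32 was 0.1094; leaving out organellar genes gave -1.124 in L1 but hardly moved the scaling. Plastid share would move all nuclear genes alike, so it alone would not put the list at -1.13 relative to the median of all genes in L1; a fall in absolute amount was not tested. Genes matched for length, GC content and level had medians of -0.4819 (photosynthesis) and -0.6036 (ribosome) in L1, so such properties could carry part of both changes, and of the ribosomal change in limyb-32 (matched -0.4958) all of it. In L3 the lowest of 200 draws of matched genes was -0.804 for photosynthesis and -0.7529 for the ribosome, both above the lists' medians. Photosynthesis genes were as low in limyb-32 (-0.96), and L1 and L3 did not pass against it (-0.08 and 0.11). Root RNA may add to the fall in limyb-32, so a role of LIMYB stays open. Ribosomal genes fell further in the lines, but plant pools and insertion differ too, so a role of LIMYB there stays untested.

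Root markers were higher in all 3 groups than in Col-0 although the labels give leaf tissue. In the further root list, none of whose 25 genes is in another list, 84% rose in the libraries labelled limyb-32, as root tissue in those pools would give, and 60% rose in both lines, which leaves it open there. Root RNA in the pools may thus be part of the change in limyb-32. No biological explanation was tested.

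That some groups differ is beyond chance (16733 genes, highest other 4736), with 1 of 60 drawn assignments as large. Single genes are not covered. The 11090 genes shared by the lines and 4147 reversed in both (highest other 0 each) only restate this difference. Sharing or reversal beyond the shared libraries was not tested. For 3 against 3 libraries the 10 splits are too few; the real counts and highest others were 12408 and 0 (limyb-32 against Col-0), 12928 and 0 (L1), 12698 and 0 (L3), 10742 and 0 (L1 against limyb-32), 10424 and 0 (L3 against limyb-32) and 774 and 5 (L3 against L1). For the absolute ribosomal median they were 0.42 and 0.20, 0.99 and 0.39, 1.16 and 0.45, 0.60 and 0.28, 0.76 and 0.33, and 0.15 and 0.15 in the same order. For photosynthesis they were 0.96 and 0.39, 1.11 and 0.50, 0.91 and 0.37, 0.08 and 0.28, 0.11 and 0.13, and 0.20 and 0.29, with 8, 2 and 3 of 10 splits as large in the last 3 and 2 of 10 for the ribosomal median of L3 against L1.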
